A study of Oryzias minutillus with 2 samples.

How the data were processed

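Whole bodies of the Thai medaka Oryzias minutillus, a small freshwater ricefish of the family Adrianichthyidae, were profiled by RNA sequencing in 1 male and 1 female sample. Total RNA was treated with DNase I and extracted with a column kit, per the labels' protocols, and sequenced on an Illumina HiSeq 2500, per the series' design text. The title describes a de novo transcriptome, so sequences were assembled from the reads without a reference genome. The design text speaks of triplicate sequencing. The labels list 1 sample per sex, and whether a sample pools several animals or runs is not given in the sources used here. The population part of the study that its title names was not analysed here.

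The authors deposited one FPKM value per assembled cluster and library (fragments per kilobase of cluster per 1000000 mapped fragments), rounded to 2 decimals, per the file headers and the values. CASAVA 1.8, Illumina software that includes demultiplexing, is the tool named in the submitters' processing notes. The assembler, the clustering step, the aligner, the counting tool and any filter are not given in the sources used here. Each sample came with 2 files that were byte for byte the same, and 1 of them was used. Both libraries list the same 73551 cluster identifiers. The FPKM values sum to 1009910 in the male and 1007824 in the female library, which exceeds 1000000 by 9910 and 7824. Rounding can move such a sum by at most 368, so the values are not TPM. FPKM puts libraries on the scale of an equal number of mapped fragments, and a few very abundant transcripts in one library lower the FPKM of every other cluster there.

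Read counts, cluster lengths, sequences and gene names were not used here. Identifiers such as those of the clusters named in the results are assembly numbers and give no gene identity. Therefore no genomic position, exon or function could be attached, and the 17 gene lists fixed beforehand (sex differentiation, egg coat, sperm flagellum and others) were not used. The design had assumed read counts, with trimmed-mean scaling and exact count intervals. With FPKM alone, the values were compared as deposited on a log2 scale with a pseudocount of 1, and the trimmed-mean scaling became an alternative. A fold on the log2(FPKM + 1) scale understates the difference of low-abundance clusters. A cluster below 3 FPKM in both libraries cannot differ by 4-fold on that scale, however large its ratio.

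With 1 library per sex, no spread between animals can be estimated. No p-value was computed, and each difference describes these 2 libraries and has no replicate check. Clusters were counted by a fixed rule of size, a difference of at least 2 in log2(FPKM + 1), which is 4-fold on that scale. A cluster was called abundant at 100 FPKM or more in the higher library. Clusters seen in one library needed at least 1 FPKM there and a listed value of 0 in the other. The Pearson correlation used log2(FPKM + 1) of clusters with a mean of at least 1 FPKM. The rule for named clusters, set for identifiers without gene names, was the 2 per direction with the most extreme difference. The interval bound that the rule ranks on needs counts, so the difference in log2(FPKM + 1) was ranked instead.

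The number of reads behind each library is unknown, so no counting interval or detection floor can be given, and a listed 0 does not show absence. A hint on relative depth came from clusters of 2 to 12 FPKM, whose male to female ratios should gather at simple read ratios if whole reads were counted. Such ratios gathered at a log2 offset of 0.0175 (bootstrap 95% interval over clusters 0.015 to 0.02, 200 resamples, offsets up to 0.15 searched), with 693 clusters in the windows against a median of 531 over all offsets. Clusters whose male and female values were equal or stood at exactly a simple ratio had been left out, since rounding can give such values. Equal depth would give such values too. The interval limits are neighbouring steps of the offsets tried, each with a window of 0.015 to either side. If whole reads were counted, the best offset corresponds to reads worth 1.22% more FPKM in the male library, but equal worth is not excluded. Depths apart by a simple factor, or by more than the offsets searched, would not show in this search, so depth stays unknown.

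Alternatives were 4 other scalings, a 2-fold threshold, other pseudocounts, filters on low values, other detection minimums and another correlation coefficient. The weighted trimmed mean left out 30% of ratios and 5% of abundances at each end, with FPKM in place of counts in the weights. The fold threshold, the scalings, the number of top clusters and the pseudocount of the correlation were fixed before the data were examined. The use of FPKM without further scaling as the main comparison, its pseudocount, and all FPKM minimums were set after the files proved to hold no counts. The code was tested on simulated data for the male to female comparison over 73551 clusters, with an assumed depth. It recovered 200 of 200 clusters changed 8-fold, called 0 unchanged clusters, and returned a scaling shift of 0.2628 where 0.263 had been set. The changed clusters had a mean of at least 10 FPKM, only counting noise was simulated, and the trimmed-mean scaling was applied. The simulation therefore checks that the code runs correctly. It gives no error rate for low-abundance clusters or for those listed at 0 in 1 library. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.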

Results

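The transcriptomes of 1 male and 1 female whole-body library of Oryzias minutillus were compared over 73551 clusters of a de novo assembly. Most clusters were detected in both sexes. In the male library, 65397 clusters (88.9%) had a value above 0, and in the female library 64026 (87.0%). Values above 0 in both libraries were listed for 59382 clusters, in the male library alone for 6015 and in the female library alone for 4644. A further 3510 clusters (4.77%) were listed at 0 in both. At 1 FPKM or more, 48019 clusters were present in the male and 42234 in the female library. At 10 FPKM or more, the order turned, with 9262 in the male and 9402 in the female library. There was 1 deposited library per sex, so none of the values below carries a replicate error, and sequencing depth is unknown. Whether a library pools several animals or runs is not known.

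A small set of clusters made up a large part of each library. The 100 most abundant clusters held 37.9% of the summed FPKM in the male and 35.4% in the female library, and the 10 most abundant held 11.3% and 8.74%. Of the 100 most abundant clusters of each sex, 75 were the same. Among the 100 of the female library, 16 were at least 4-fold higher there than in the male on the log2(FPKM + 1) scale. Among the 100 of the male library, 0 were at least 4-fold higher in the male. Across the 46740 clusters with a mean of at least 1 FPKM, Pearson's r of log2(FPKM + 1) between the sexes was 0.73 and Spearman's rho was 0.61. Both describe agreement across clusters, which are not independent replicates.

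The labels separate the samples by sex, so the comparison asks which transcripts differ between the male and the female whole-body sample. The clusters at least 4-fold higher in the female library held a larger part of its expression than the male-higher clusters held of the male library, while which set was the more numerous depended on the settings. On the log2(FPKM + 1) scale, 1510 clusters (2.05%) were at least 4-fold higher in the male library and 1704 (2.32%) were at least 4-fold higher in the female library. Among clusters of 3 to 10 FPKM in the higher library, these shares were 5.82% and 5.20%. The shares of all clusters are lower because they count clusters below 3 FPKM in both libraries, which cannot reach 4-fold on this scale. The male-higher clusters held 2.64% of the summed FPKM of the male library and 0.252% of that of the female library. The female-higher clusters held 14.9% of the summed FPKM of the female library and 0.391% of that of the male library. Of the male-higher clusters, 1102 were listed at 0 in the female library, and of the female-higher clusters, 1068 were listed at 0 in the male library. Most clusters of either set were thus listed at 0 in the other library, where the detection limit is unknown. The median of the higher value was low in both sets, at 6.03 FPKM in the male-higher and 8.42 FPKM in the female-higher clusters. With a weighted trimmed mean of the ratios as scaling, which shifts the log2 ratios by 0.21 toward the female library, the counts were 1200 male-higher and 1809 female-higher clusters. The order of the counts turned with a 2-fold threshold (8881 male-higher and 5959 female-higher) and with a pseudocount of 0.1 (8682 and 6078). The female-higher set was the larger by a wider margin with a pseudocount of 5 (207 male-higher and 460 female-higher), with a mean of at least 10 FPKM (184 and 469), and among clusters above 0 in both libraries (408 and 636).

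**Figure D1:**
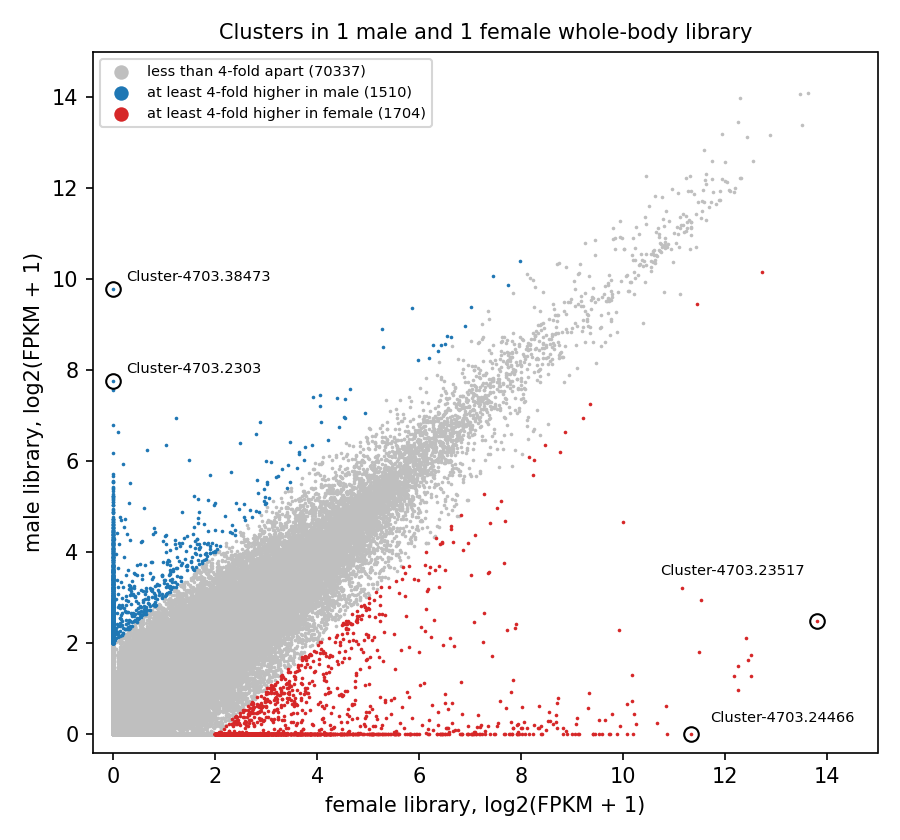
Each point is 1 of the 73551 clusters, with log2(FPKM + 1) in the female library on the horizontal axis and in the male library on the vertical axis. Blue points (1510) and red points (1704) are at least 4-fold higher in the male and female library on this scale, open circles mark the 4 named clusters, and the red points reach 14463.57 FPKM while the blue points reach 1340.87 FPKM.

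Among abundant clusters, female-higher ones outnumbered male-higher ones. Of the 1159 clusters with at least 100 FPKM in the higher library, 163 (14.1%) were at least 4-fold higher in the female and 33 (2.85%) in the male library. With a 2-fold threshold these counts were 218 and 122. The 163 female-higher clusters alone held 12.8% of the summed FPKM of the female library and 0.293% of that of the male library. Their median in the male library was 0.16 FPKM, and 55 of them were listed at 0 there. The 33 abundant male-higher clusters held 1.21% of the summed FPKM of the male library, their median in the female library was 29.8 FPKM, and 4 of them were listed at 0 there. A difference of at least 32-fold on the log2(FPKM + 1) scale was found for 225 female-higher and 33 male-higher clusters, of which 136 and 5 were abundant. At 1000 FPKM or more, 25 of 194 clusters were at least 4-fold higher in the female library and 2 in the male library. At least 32-fold, these were 23 in the female and 0 in the male library.

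**Figure D2:**
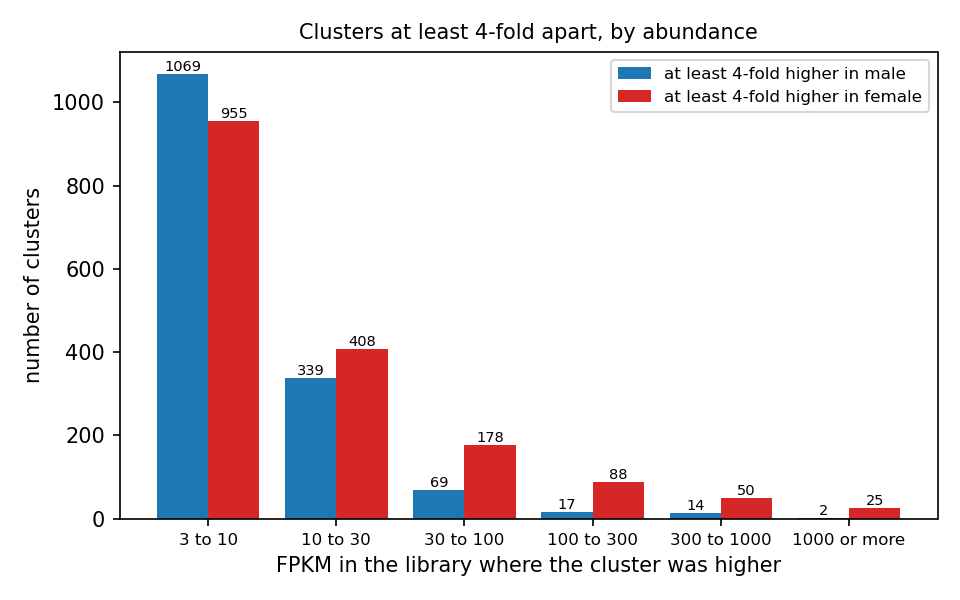
Bars count the clusters at least 4-fold higher in the male (blue) or female (red) library on the log2(FPKM + 1) scale, by FPKM class of the higher library. Male-higher clusters outnumber female-higher ones from 3 to 10 FPKM (1069 against 955), and female-higher ones are the more numerous in every class above that, with 88 against 17 from 100 to 300 FPKM. The counts use FPKM as deposited, and the classes were not recounted under the other scalings.

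The most extreme clusters on the female side were Cluster-4703.24466 and Cluster-4703.23517. Cluster-4703.24466 had 2606.23 FPKM in the female library, where it ranked 55 by abundance, and was listed at 0 in the male. Cluster-4703.23517 was the most abundant cluster of the female library at 14463.57 FPKM and had 4.62 FPKM in the male, a ratio of 3131 and a log2 ratio of 11.61. On the male side, Cluster-4703.38473 had 875.65 FPKM in the male library, where it ranked 173, and was listed at 0 in the female. Cluster-4703.2303 had 216.08 FPKM in the male library, where it ranked 479, and was also listed at 0 in the female. No gene name or sequence was attached to these identifiers here.

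Clusters detected in one library alone were more numerous on the male side at a minimum of 1 FPKM. They are not a separate set, since those of at least 3 FPKM are always part of the 4-fold sets above. At least 1 FPKM in the male library and 0 in the female was listed for 3512 clusters, and the reverse for 2608. At a minimum of 5 FPKM the order turned, with 583 clusters in the male library alone and 659 in the female library alone. At a minimum of 100 FPKM, the male library alone had 4 such clusters and the female library alone had 55.

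Low-abundance clusters as a whole were higher in the male library, while those of middle and high abundance were centred near equality. Among clusters above 0 in both libraries, the median log2 ratio of male to female was 0.42 at a mean of 0.3 to 1 FPKM, 0.41 at 1 to 3 FPKM and 0.14 at 3 to 10 FPKM. It was -0.02 at 10 to 30 FPKM, 0.06 at 30 to 100 FPKM and 0.09 at 100 FPKM or more. The male value was the higher one in 62.9% of clusters at 1 to 3 FPKM and in 48.5% at 10 to 30 FPKM. The interquartile range of the log2 ratio narrowed from 1.86 at 0.3 to 1 FPKM to 0.78 at 100 FPKM or more. This is a spread between clusters, which mixes differences between the libraries with counting error. These medians refer to FPKM as deposited. With the weighted trimmed mean as scaling, each is lower by 0.21, which places the classes from 3 FPKM upward on the female side and leaves those below 3 FPKM on the male side.

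**Figure D3:**
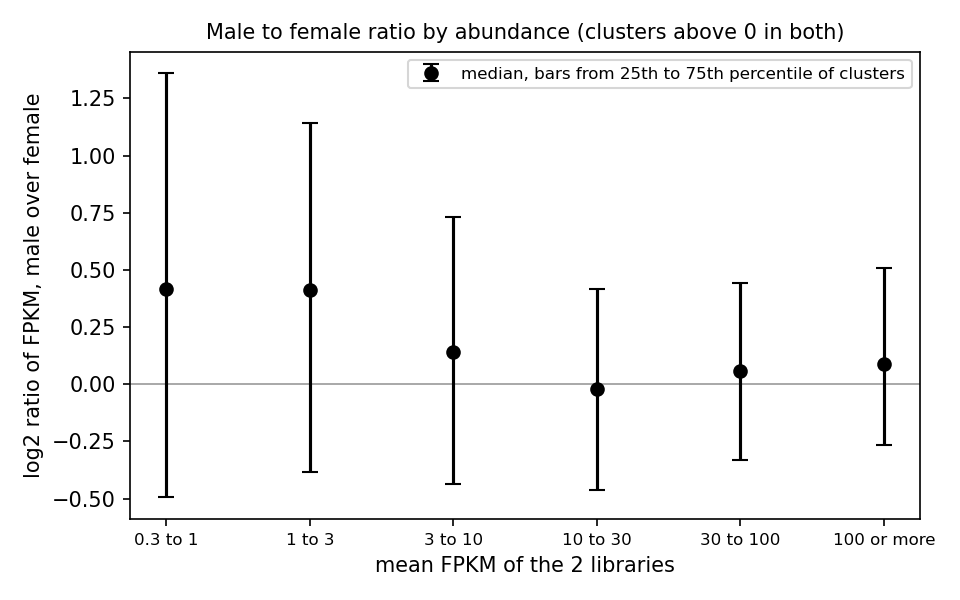
Points show the median log2 ratio of male to female FPKM over clusters above 0 in both libraries, by the mean FPKM of the libraries, and bars run from the 25th to the 75th percentile of clusters. The median is 0.41 at 1 to 3 FPKM and -0.02 at 10 to 30 FPKM.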

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

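The 4 other scalings gave 1169 to 1529 male-higher and 1692 to 1824 female-higher clusters, and 24 to 34 and 160 to 170 among those of at least 100 FPKM, all within 1.5 times the values reported. Several other settings moved the values further, and some changed which side was the larger. A 2-fold threshold gave 8881 male-higher and 5959 female-higher clusters, so the male side was then the larger, and among those of at least 100 FPKM 122 and 218, so the female excess there was smaller than at 4-fold. The 10 most abundant clusters held 11.3% and 8.74% of the summed FPKM in the male and female library. The correlation across clusters was 0.54 with a pseudocount of 0.1, 0.80 without the filter on low values, and 0.61 as Spearman's rho. The class of at least 100 FPKM and other pseudocounts, FPKM filters and detection minimums for the counts of clusters were chosen after seeing the data. A pseudocount of 0.1 gave 8682 male-higher and 6078 female-higher clusters, again with the male side larger, and a pseudocount of 5 gave 207 and 460. A mean of at least 10 FPKM left 184 and 469, and clusters above 0 in both libraries numbered 408 and 636, with 108 abundant female-higher ones. Clusters listed in the male or the female library alone numbered 6015 and 4644 at any value above 0, 583 and 659 from 5 FPKM, 228 and 316 from 10 FPKM, and 4 and 55 from 100 FPKM. Settings listed beforehand that need read counts or lengths (count filters, count intervals, thinning to equal depth, a length minimum, scaled CPM) were not run, scaling to total counts is already part of FPKM, and the gene lists were not run for want of gene names. No paired analysis was possible because each sex has 1 library. No replicate could be left out for the same reason. Because depth is unknown, a listed 0 has no known detection limit.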

Other observations

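The tests of explanations in this part, the class of at least 100 FPKM and the abundance classes were chosen after the values were seen, while the scalings and the 2-fold threshold were fixed beforehand. The clusters are unevenly grouped by the first number of their identifier. Of 16703 such groups, 13994 have 1 member, while the largest holds 52612 clusters (71.5% of all) with 96.8% of the summed FPKM in the male and 97.3% in the female library. All 163 abundant female-higher and all 33 abundant male-higher clusters belong to it. With so much of the summed FPKM in this group, the same may hold for abundant clusters in general, whose share there was not counted. In the largest group, 2.69% of clusters were at least 4-fold higher in the female and 2.14% in the male library on the log2(FPKM + 1) scale. Outside it the order was the other way, with 1.38% in the female and 1.83% in the male library. The clusters outside hold only the small rest of the summed FPKM, and these shares were not matched on abundance. In 804 small groups with exactly 2 clusters of at least 1 FPKM on average, the male to female differences of the pair members correlated (intraclass r = 0.40, against at most 0.11 in 1000 random pairings of the same clusters). These pairs do not cover the largest group, and whether members of a pair come from the same transcript was not tested. Since the male to female ratio varied with abundance, like abundance of the members could contribute, and no comparison at matched abundance is given.

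Abundant clusters at least 4-fold apart lay mostly on the female side (163 against 33). The choice among the 5 scalings used is argued against, because the lowest ratio of female-higher to male-higher abundant clusters over them was 4.71. Log2 shifts of 0.0966 to 0.229 lower the male values and can only raise this ratio. The only shift the other way was -0.0141, so a larger scaling error in that direction was not tested. The size of the excess depends on the threshold, since at 2-fold the counts were 218 and 122. A single female transcript split over the whole set is argued against, because fragments of 1 transcript would share a female to male ratio, and for the best shared ratio tried (11.1 on the log2 scale) 44 of the 163 clusters had a male value more than 4-fold off. Values below 0.5 FPKM counted as matching where less than 0.5 FPKM was predicted. A listed 0 counted as off where more was predicted, although its detection limit is unknown. Counting error was not allowed for, so it may account for some of the 44. The share of matches required of a single transcript was also set after the values were seen. The other 119 matched it, most easily those near 0 in the male library, which match any high ratio, so for these 119 a single split transcript or a few stay open, as do the sex of the animals, their reproductive state and any other difference between 2 unreplicated samples; matching the cluster sequences to egg-coat, yolk-protein and oocyte genes would be a direct test, not run here.

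The lean of low-abundance clusters to the male library was also weighed. Dilution of the female library by its abundant transcripts is argued against as the sole cause, because it would move every other cluster by the same factor. The median log2 ratio at 1 to 3 FPKM exceeded that at 10 FPKM or more by 0.401 (bootstrap 95% interval over clusters 0.376 to 0.414; medians 0.41 and 0.01), and other classes and zero handling gave 0.26 to 0.40. The interval treats clusters as independent, so it may be too narrow, and it measures no spread between libraries. The class of 10 FPKM or more includes the abundant clusters themselves. A class of 10 to 30 FPKM on average cannot hold a cluster of at least 100 FPKM, and its median was -0.02. A deeper male library stays open. Simple read ratios gathered at a log2 offset of 0.0175 (0.015 to 0.02), but the search reached only offsets of 0.15 and left out values at exact simple ratios. It also assumes whole reads and would miss depths apart by a simple factor. A wider range of genes at low level in the male body (a testis, for example, is known to transcribe many genes) and more unspliced RNA or residual DNA in the male library were not tested and stay open.

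That 3510 clusters are listed at 0 in both libraries is unexpected for an assembly made from sequenced reads. Rounding to 2 decimals is argued against, since 31 clusters had both values at most 0.02 without both being 0. Assignment of reads to similar clusters cannot be told apart from other reasons. The share listed at 0 in both was 4.82% in groups with several members and 4.56% in groups with 1 member, a ratio of 1.06, but no source states that a group number marks similar sequences. Clusters too short for the authors' length correction, or assembled from libraries other than these 2, were not tested.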
